A study of Folsomia candida with 36 samples.

How the data were processed

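Data were processed from 1 deposited table of 28734 gene models by 36 libraries. Per the labels' protocols, RNA was extracted with TRIzol from pools of whole animals, and stranded mRNA libraries were made from it with a TruSeq kit. Per the same protocols, the authors trimmed reads with Trim Galore, which wraps Cutadapt (version given as 0.6.7), assigned them to the transcriptome with Salmon 1.4.0 and normalized them with DESeq2 1.28.1. The transcriptome release is not given in the sources used here. The deposited values are estimated counts per gene model, and they differ in total between libraries, from 20280135 to 42146055, so they were treated as counts before normalization. All values were whole numbers as deposited (0 were not), so rounding changed none of them. The 17 largest values, those with 7 digits, all ended in 0, so the largest counts carry fewer digits. Salmon divides reads between similar transcripts by estimation, so counts of near-identical gene copies are uncertain.

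Groups were taken from the treatment and time in the labels. The titles carry a replicate number for each library. In the 72 h imidacloprid group 2 libraries carry the number 4 and are told apart here by their library numbers, 71 and 72. The chi-square per degree of freedom between them was 104.6, within the range of 20.7 to 341.9 over the 36 pairs of libraries of a group, so they were not taken as copies of the same library and were counted as 2 replicates. The run without irregular titles left out imidacloprid 12 h replicate 5, whose title has no library number, and imidacloprid 60 h replicate 1, whose number 34 is out of order, and summed the libraries numbered 4. Other irregular numbers were left in: imidacloprid 12 h replicate 6 has the number 2, as has control 12 h replicate 2, and control 24 h replicates 3, 4 and 6 have the numbers 5, 4 and 8, the last shared with imidacloprid 12 h replicate 2. Same-numbered libraries of both treatments at a time point gave no sign of deviating together, so replicate numbers were not used as pairs.

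The gene identifiers were searched in a gene table of the species with 27231 genes, and 0 were found there. The deposited table does not pair identifiers with names, so gene products, coordinates and sequences are not used here, and the tests of gene lists that had been fixed by product name were not run. The rule for named genes, fixed before the data were examined, required a mean of at least 1 CPM and took the largest changes past the threshold: over all time points with the same sign at all 6, at a single time point with all 3 exposed libraries outside the range of the controls, and between 72 and 12 h in controls. It also took the genes called in the same direction at the most time points. Largest changes between alternate time points in controls were part of the rule too, but no called gene there reached 1 CPM. The rule asked for an informative product name in every part, which could not be applied. Its part on members of gene lists was not used, since the lists rest on names. The parts on the smallest p of the change over time and on genes that do not pass were not used either. Without product names at most 2 identifiers per direction were given for each comparison. Exceptions are genes of lists with 5 or fewer calls, a gene called both over all time points and between 72 and 12 h in controls, and called genes with consecutive identifiers, and all are marked as chosen after their values were seen.

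Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19600 genes (68.2%) holding 99.97% of the counts. Libraries were scaled by TMM, with factors from 0.89 to 1.103. A quasi-likelihood model with robust dispersion estimates was fitted to all 36 libraries with a mean for each of the 12 groups, which gave 24 residual degrees of freedom. The biological coefficient of variation was 36.5%. P-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The comparisons were imidacloprid against control at each time point and as the mean over the 6 time points, the change of that effect over time, the time points in controls, 72 against 12 h in controls, and alternate time points in controls and their change with imidacloprid. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM values a prior count of 2. The 3 counts behind the floor cover counting error only.

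Sets of genes were tested by fry in limma 3.58.1. Variance shares are sums of squares of log2 CPM over all tested genes. With 3 libraries against 3, an exact permutation test cannot give a share under 0.1, so single time points have no such test of their own. The co-varying set is the largest cluster (complete linkage on 1 minus the correlation, height 0.5) of the 171 genes with a variance of log2 CPM above 4.

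The steps were tested on simulated data drawn from the means, dispersions and library sizes of the 19600 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For imidacloprid over all time points, 79% of the 2-fold and 95% of the 4-fold changes were called, with 8 unchanged genes. For imidacloprid at 48 h it was 27% and 68%, with 3 unchanged genes. For a change at 48 h among the time points in controls it was 20% and 63%, with 0 unchanged genes. With no gene changed, 0 genes were called in each of the 12 comparisons. The draws were independent between genes, so variation shared by many genes of a library, as present in these data, was not simulated. These rates therefore do not show how many false calls such variation gives.

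The alternatives tried were DESeq2 1.42.0 as the test, its size factors in edgeR, limma-voom, no filter on low counts, a filter at 5 CPM in 3 libraries, a block for the replicate number, 1 surrogate variable (sva 3.50.0), fits of only the 6 libraries compared, the 2 libraries numbered 4 summed, and each library left out in turn. Added after the data were examined were 2 surrogate variables, the level of the co-varying set as a covariate, limma-voom with a weight per library, no scaling beyond library totals, a run without the libraries with irregular titles, correlations without the co-varying genes, and the response of genes called from 5 time points at the time point left out.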

Results

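Whole-body gene expression was measured by RNA sequencing in the springtail Folsomia candida, a soil-dwelling hexapod used as a test organism in soil toxicology. Pools of 70 animals of the Berlin strain were placed on a natural soil that held either imidacloprid at 0.25 mg per kg dry soil or water alone. Imidacloprid is a neonicotinoid insecticide that acts on nicotinic acetylcholine receptors, and the labels give this concentration as the one that lowers reproduction by 20% (EC20). Samples were taken every 12 h up to 72 h. The design therefore had 2 treatments, 6 time points and 3 libraries in each of the 12 groups, 36 libraries in all. Total counts per library ranged from 20280135 to 42146055, with a median of 25542483. A gene with 3 counts in the smallest library stood at 0.148 counts-per-million (CPM), which is taken as the floor of detection for counting error. The labels put the pools in glass jars and say no more on how replicates were made. Libraries were taken as separate pools, so p-values measure the spread between pools of animals. Of the 28734 gene models in the table, 19600 had enough counts to be tested. Genes are given by the identifiers of the deposited table, which does not pair them with names or positions.

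The share of variance that went with time was above that of shuffled labels, and the share that went with treatment did not pass this test. Over the 19600 tested genes, time point accounted for 22.1% of the variance of log2 CPM, against a median of 14.1% when time labels were shuffled within treatments (permutation test, 100000 permutations, p = 0.0039). Treatment accounted for 2.59%, and shuffling the treatment labels within time points gave a median of 2.34% (permutation test, p = 0.40). The change of the treatment effect with time accounted for 15.7%, where 14.3% would arise with no effect of time or treatment. Since time took more than that share, this reference is too high for the change, which had no permutation test. Differences between libraries of the same group made up 59.6%, below the 68.6% of data with no effect of time or treatment.

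**Figure D1:**
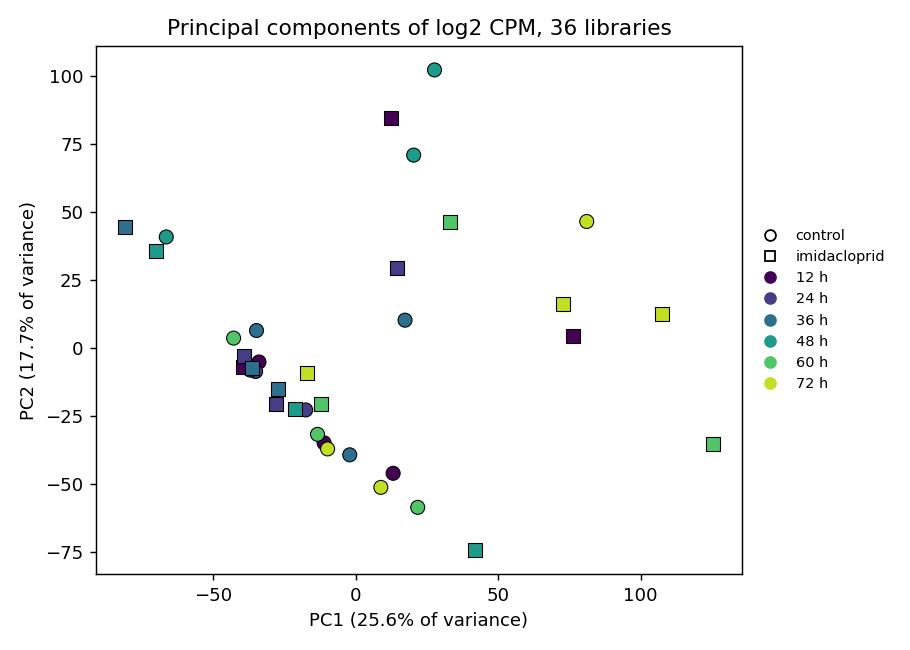
Each point is a library placed by its first 2 principal components of log2 CPM (axes in component units, with the percent of variance), with color for the time point in h, circles for controls and squares for imidacloprid. The treatments overlap on both axes, which hold 25.6% and 17.7% of the variance.

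A set of 108 genes that varied together set 11 libraries apart from the rest, in both treatments. Its mean log2 CPM was between -3.21 and -2.60 in 25 libraries. It was -0.45 in control 36 h replicate 5, and between 1.18 and 3.20 in 10 others: imidacloprid 12 h replicates 2 and 6, imidacloprid 24 h replicate 3, control 48 h replicates 2 and 6, imidacloprid 60 h replicates 3 and 5, control 72 h replicate 5, imidacloprid 72 h replicate 1 and library 71 of imidacloprid 72 h replicate 4. The set took between 0.000829% and 0.183% of all counts. None of its genes was called in the comparisons of imidacloprid with control (edgeR, adjusted p), and 3 were called between the time points in controls. Beyond the 108, another 587 tested genes had a correlation over 0.8 with the mean level of the set. The set of 108 was defined after the data were examined.

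**Figure D2:**
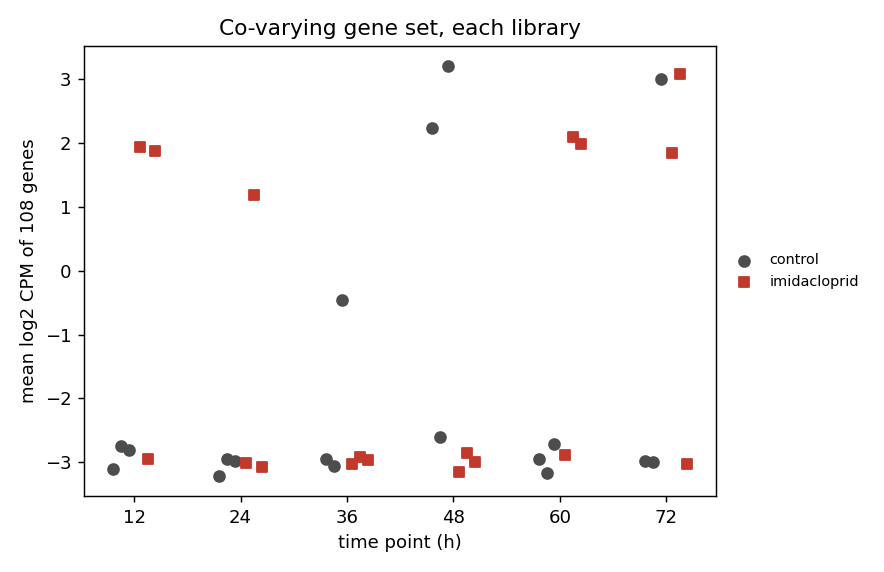
Mean log2 CPM of the 108 co-varying genes (y axis) in each of the 36 libraries by time point in h (x axis), with circles for controls and squares for imidacloprid. The levels lie at or below -2.60 in 25 libraries and at or above 1.18 in 10, with control 36 h replicate 5 between them at -0.45.

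The comparison of imidacloprid with control over all time points asks which genes differed with exposure when the 6 time points are weighted equally. Exposed animals had higher expression of 33 genes and lower expression of 27 (edgeR quasi-likelihood test, 60 genes with a Benjamini-Hochberg adjusted p under 0.05). In this comparison 645 genes had an unadjusted p under 0.05, where 980 would by chance. No wide excess of small p-values therefore stands behind the 60 calls. Among called genes with a mean of at least 1 CPM that differed in the same direction at every time point, Fcan01_10767 had the largest rise, with a log2 fold change of 1.98 ± 0.18 (SE), a 3.94-fold higher level (edgeR adjusted p = 5.84e-08). Fcan01_25348 followed, with 1.91 ± 0.33 (3.77-fold, edgeR adjusted p = 0.00379). The largest fall among such genes was that of Fcan01_09015, at -1.89 ± 0.37 (3.72-fold lower, edgeR adjusted p = 0.0145). Fcan01_20402 came next at -1.84 ± 0.27 (3.58-fold lower, edgeR adjusted p = 0.000556). Called genes below 1 CPM, 8 higher and 5 lower, are not named, and differences among all 60 reached sizes of 3.18 in the higher and 2.17 in the lower genes. Fcan01_25348, Fcan01_09015 and Fcan01_20402 had mean levels of 1.51, 1.05 and 1.13 CPM. Fcan01_09015 stood at 0.14 CPM at 24 h with imidacloprid, with 3 to 6 counts per library. That mean lies under the floor of 0.148 CPM, so the size of its fall is uncertain. Fcan01_20402 stood at 0.169 CPM at 72 h with imidacloprid, with 2 to 9 counts per library. This is near the floor, so the size of its fall is uncertain too. The calls for Fcan01_25348 and Fcan01_09015 were lost with limma-voom, where their log2 fold changes were 1.73 and -1.82.

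The medians of the higher genes lay further from 0 at each time point from 24 h on than at 12 h, and those of the lower genes at each but 48 h. The 33 higher genes had a median of 5.83 CPM and the 27 lower genes one of 3.64 CPM over all libraries. The median log2 fold change of the 33 higher genes was 0.14 at 12 h, 1.37 at 24 h, 1.09 at 36 h, 2.46 at 48 h, 1.72 at 60 h and 1.56 at 72 h. For the 27 lower genes it was -0.60, -2.07, -1.89, -0.46, -1.46 and -1.31 at the same times. The difference had the same sign at all 6 time points in 19 of the 33 higher genes and in 23 of the 27 lower genes. These genes were chosen on the same libraries, so their profile describes the calls. DESeq2 called 64 higher and 58 lower genes, and the filter at 5 CPM in 3 libraries left 19 and 13. A block for the replicate number left about as few genes in all as this filter. The balance turned to more lower genes with 1 surrogate variable (44 higher, 84 lower), with 2 (43 and 73), with library-weighted limma-voom (93 and 120) and with the level of the co-varying set in the model (21 and 24). It also turned without imidacloprid 48 h replicate 5 (29 and 44), without imidacloprid 12 h replicate 2 (25 and 27), without imidacloprid 36 h replicate 2 (25 and 29) and without control 60 h replicate 5 (26 and 33). It went the other way without imidacloprid 48 h replicate 3 (43 and 25) and without the libraries with irregular titles (33 and 14).

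At the single time points, edgeR called genes at 48, 60 and 72 h, and 4 genes were called higher at each of these: Fcan01_10767, Fcan01_17452, Fcan01_08638 and Fcan01_17957. Independent lists of these sizes would share 0.0014 genes between 48 and 60 h. The lists come from the same fit with a shared spread estimate for each gene, so they are not independent even with no effect. All 4 did not recur in every alternative. Fewer than 4 genes were called at 48 h without control replicate 4 or 6 or imidacloprid replicate 5 (3 each), and at 60 h without control replicate 2, 5 or 6 or imidacloprid replicate 3 (3 each). The same held at 72 h for the left-out libraries given with that time point and without irregular titles, and in fits of only the 6 libraries at 48 and 60 h. It also held with a block for the replicate number at 48 and 72 h. With the level of the co-varying set in the model, Fcan01_17452 lost its call at 60 h. Other tools also called genes at earlier times. Fcan01_17957, the most highly expressed of the 4, stood at 36.7 CPM ± 5.16 (SD, n = 3) in controls and 257 ± 132 with imidacloprid at 48 h. At 72 h it stood at 72.3 ± 11.8 and 364 ± 36.5. Its log2 fold change was -0.02 ± 0.33 (SE) at 12 h, 0.65 ± 0.33 at 24 h and 1.09 ± 0.33 at 36 h, none of which passed the test. It then reached 2.81 ± 0.35 at 48 h, 2.41 ± 0.34 at 60 h and 2.33 ± 0.34 at 72 h. Fcan01_17452 went from 36.6 CPM ± 11.3 in controls and 34.7 ± 18.1 with imidacloprid at 12 h to 38.4 ± 6.31 and 208 ± 31.4 at 72 h. Fcan01_08638 stood at 4.62 CPM ± 0.627 in controls and 18.5 ± 3.70 with imidacloprid at 72 h.

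**Figure D3:**
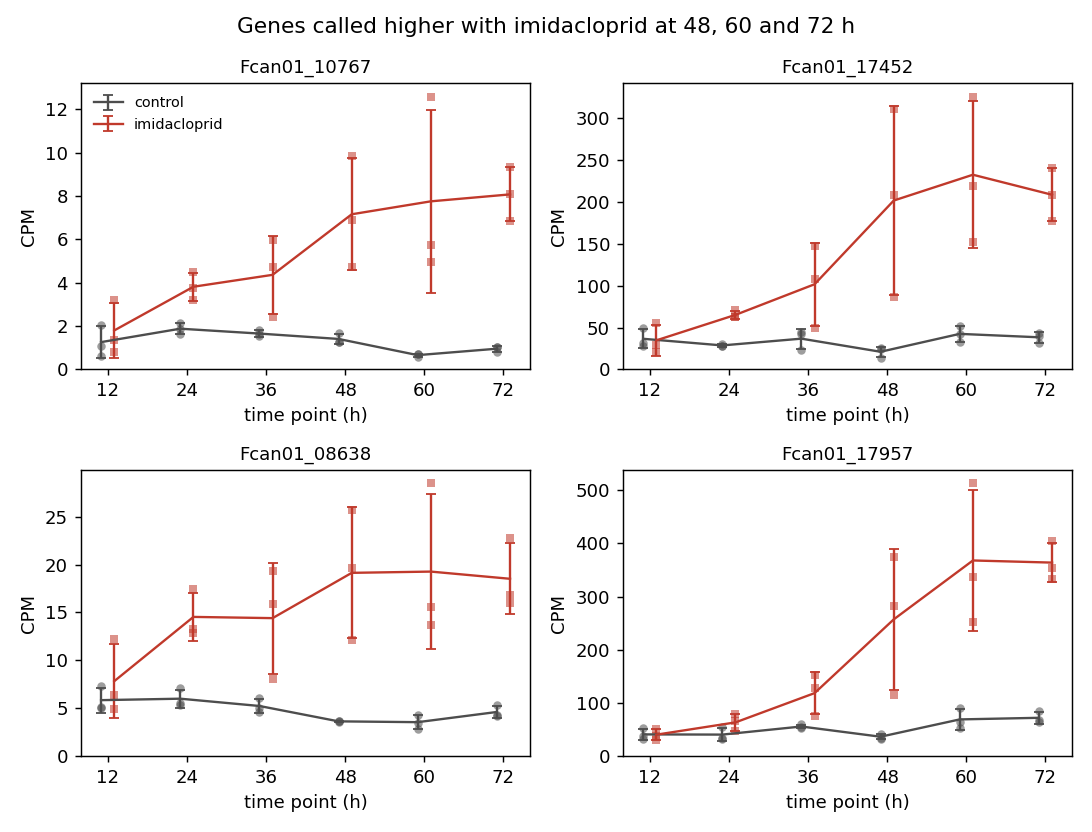
CPM (y axes, from 0) by time point in h (x axes) of the 4 genes called higher at 48, 60 and 72 h. Points are libraries, circles for controls and squares for imidacloprid, and lines join group means with bars of 1 SD (n = 3). Means with imidacloprid lie above those of controls from 24 h on, and Fcan01_17957 reached 364 CPM against 72.3 at 72 h.

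At 48 h, edgeR called 7 genes, all higher with imidacloprid, whereas DESeq2 called 22 higher and 31 lower and library-weighted limma-voom 1757 and 1860. Fcan01_17452 had the largest difference among edgeR's calls of at least 1 CPM whose exposed libraries all lay above the controls, at 3.25 ± 0.43 (SE) in log2 units (9.54-fold, edgeR adjusted p = 0.000351). Fcan01_27829 was next at 3.17 ± 0.58 (9-fold, edgeR adjusted p = 0.0254). It lost its call with limma-voom and with 2 surrogate variables, where the log2 fold change fell to 2.05. In all, 2819 genes had an unadjusted p under 0.05, where 980 would by chance, and 1830 of them were higher and 989 lower with imidacloprid. Without imidacloprid replicate 5 this number was 814, below the 980, and without imidacloprid replicate 3 it was 6127, so single libraries set this excess. Without control replicate 4 or 6 it was 1866 and 1762. The median log2 fold change of all tested genes at 48 h was 0.113 and moved by -0.125 with DESeq2 size factors, which left the 7 calls in place. Leaving out imidacloprid 48 h replicate 3 raised the number to 24, leaving out control replicate 4 or 6 or imidacloprid replicate 5 lowered it to 3, and leaving out control replicate 2 or imidacloprid replicate 6 lowered it to 4. Fitted to all 36 libraries, DESeq2 called 53 and limma-voom 5. An edgeR fit of the 6 libraries alone called 0 (678 at an unadjusted p under 0.05); the other tools were not fitted to these alone.

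At 60 h, the 4 recurring genes were the only calls by edgeR. Fcan01_10767 stood at 0.662 CPM ± 0.0671 (SD, n = 3) in controls and 7.76 ± 4.21 with imidacloprid, a log2 fold change of 3.54 ± 0.46 (SE, edgeR adjusted p = 0.000526). Those of Fcan01_17452 and Fcan01_08638 were 2.45 ± 0.42 and 2.44 ± 0.35. Fcan01_17452 lost its call with the level of the 108 co-varying genes in the model, at 2.20. Fitted to all 36 libraries, DESeq2 called 16 genes, limma-voom 4 and library-weighted limma-voom 68. An edgeR fit of the 6 libraries alone called 0 (403 at an unadjusted p under 0.05). In edgeR, 715 genes had an unadjusted p under 0.05, which became 375 without control replicate 2, 334 without imidacloprid replicate 3 and 1270 without imidacloprid replicate 1.

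At 72 h, edgeR called 5 genes: the 4 recurring genes were higher and Fcan01_15105 was lower with imidacloprid. Fcan01_10767 differed by 3.08 ± 0.45 (SE) in log2 units (8.45-fold, edgeR adjusted p = 0.00222), and Fcan01_17452 by 2.44 ± 0.42 (edgeR adjusted p = 0.0139). Fcan01_15105 stood at 39.4 CPM ± 6.36 (SD, n = 3) in controls and 18.4 ± 0.880 with imidacloprid, a log2 fold change of -1.10 ± 0.19 (edgeR adjusted p = 0.0174). In controls alone, Fcan01_15105 rose by 1.56 ± 0.20 in log2 units from 12 to 72 h. Fcan01_08638 and Fcan01_17957 were chosen here after their values were seen, because all calls of so short a list are given. The 72 h count fell to 0 without control replicate 4, to 2 without control replicate 3, and to 3 without control replicate 5, imidacloprid replicate 1 or library 71. No run with a library of this time point left out called more than 4 genes, so none kept all 5 calls. DESeq2 called 10 higher and 11 lower genes, library-weighted limma-voom 12 and 7, and edgeR 8 and 2 with 1 surrogate variable and 7 and 3 with 2. Without the libraries with irregular titles edgeR called 3 higher genes and 0 lower, which ended the calls of Fcan01_15105 and Fcan01_17452. Both exposed libraries at this time point that carry the number 4 entered as separate replicates, and summing them ended the call of Fcan01_15105, at a log2 fold change of -1.11.

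At 12, 24 and 36 h, edgeR called 0 genes. Genes with an unadjusted p under 0.05 numbered 649, 341 and 2032, where 980 would by chance. At 36 h the number fell to 825 without imidacloprid replicate 6, so the excess there rests on that library. Leaving out single libraries gave 283 to 1291 at 12 h, the highest without imidacloprid replicate 5, and 175 to 588 at 24 h. DESeq2 called 13, 20 and 55 genes at these times, limma-voom 0 at each, and library-weighted limma-voom 0, 61 and 998. At 36 h edgeR called 7 genes with 1 surrogate variable, 7 with 2 and 14 in a fit of the 6 libraries alone. The median standard error of a log2 fold change at a single time point was 0.37, against 0.15 over all time points. In simulated data of this design, 27% of 2-fold and 68% of 4-fold changes at 48 h were called, so differences of these sizes can be missed; other time points were not simulated with changes.

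The genes called from 5 of the time points were also read at the time point left out, a comparison added after the data were examined. Only the contrast left that time point out. Its libraries stayed in the fit, and so entered the filter, the scaling and the spread estimate of each gene. The calls are therefore not fully independent of the time point left out. At 60 h, 33 of 33 such genes went in the direction found elsewhere, at 72 h 35 of 35, and at 24 h 27 of 27. At 36 h it was 32 of 34 genes and at 48 h 35 of 44. Their median log2 fold changes in that direction were 1.47 at 24 h, 1.24 at 36 h, 0.71 at 48 h, 1.52 at 60 h and 1.56 at 72 h. These sets moved in that direction by limma's fry test, with adjusted p of 5.86e-05 at 24 h, 0.000592 at 36 h, 1.09e-05 at 48 h, and 6.57e-07 at both 60 and 72 h. A mean of log2 CPM over the set, with the sign of genes lower elsewhere reversed, was also compared. This signed mean was higher in all 3 exposed libraries than in every control at each of these 5 time points. At 48 h the genes higher elsewhere had a median of 2.58 and those lower elsewhere one of -0.23. At 12 h, 47 of 66 genes went in that direction, with a median of 0.19 (fry adjusted p = 0.382). There 1 of 3 exposed libraries lay above every control in the signed mean.

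**Figure D4:**
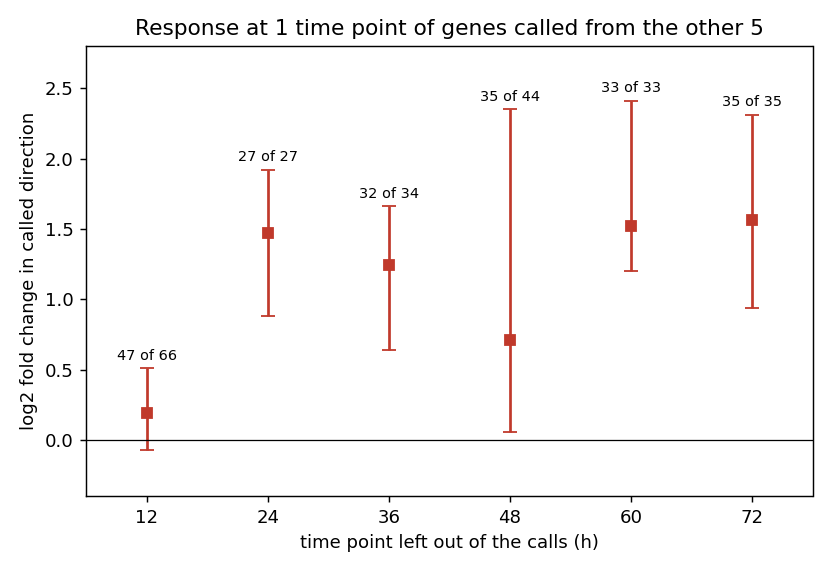
Median log2 fold change (y axis), with bars from the lower to the upper quartile over genes, at the time point in h (x axis) left out of the contrast that called the genes. Libraries of that time point stayed in the fit. Numbers above give how many genes went in the called direction, from 47 of 66 at 12 h to 35 of 35 at 72 h.

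Whether the effect of imidacloprid changed between time points was tested for each gene. EdgeR called 0 genes, with 1290 at an unadjusted p under 0.05, and the smallest adjusted p was 0.077. DESeq2 called 58 genes and limma-voom 0, and edgeR called 2 without imidacloprid 12 h replicate 2. For the response of genes called from the other 4 time points, none of the 15 pairs of time points passed the correction (exact permutation test, two-sided, 400 splits, smallest p = 0.06, smallest adjusted p = 0.405). The smallest p these splits allow is 0.005, and it is higher where both responses have the same sign, as in all 15 pairs. A single pair that differed alone could therefore not have passed over 15 pairs. The splits shuffle treatment labels within each time point, so their reference is no response at either time. Responses present at both times widen that reference, so this test cannot tell whether the response changed between them. Libraries of both time points also stayed in the fit that called the genes. The 5 pairs that set 12 h against a later time point had differences of 0.78 to 1.38 in log2 units, with exact p from 0.06 to 0.135. Across genes, log2 fold changes at pairs of time points had Pearson correlations from -0.752 (12 and 48 h) to 0.710 (12 and 60 h). The Spearman correlations of these pairs were -0.389 and 0.045. Without the 108 co-varying genes their Pearson correlations were -0.690 and 0.629. The mean log2 CPM of those 108 genes was -2.89 in controls and 0.29 with imidacloprid at 12 h. It was 0.95 and -3 at 48 h, and -2.94 and 0.4 at 60 h. Whether this uneven level sets the correlations was not tested. Genes are not independent replicates, so no p is given for the correlations.

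Expression in controls changed over the 72 h. Of the tested genes, 250 differed between the 6 control time points (edgeR F-test, adjusted p under 0.05), and 568 differed between 72 and 12 h, 382 of them higher and 186 lower at 72 h. Fcan01_02915 was higher at 72 h by 5.20 ± 1.2 (SE) in log2 units (edgeR adjusted p = 0.0183), from 6 to 9 counts per library at 12 h. Fcan01_27226 was called higher too (edgeR adjusted p = 0.00336), at 4.82 CPM ± 1.04 (SD, n = 3) at 72 h. Its 12 h mean of 0.133 CPM ± 0.0817, with 2 to 5 counts per library, lies under the floor of 0.148 CPM, so no size is given for its rise. Fcan01_06632 was 59.6-fold lower at 72 h (SE of 1.0 in log2 units, edgeR adjusted p = 0.00253). It fell from 51.5 CPM ± 14.9 at 12 h to 0.839 ± 0.415 at 72 h. Fcan01_04680 was called 63.9-fold lower (SE of 1.4, edgeR adjusted p = 0.016), but this size rests on control 12 h replicate 6, at 107.7 CPM. The other 12 h controls stood at 0.727 and 2.22 CPM and those of 72 h between 0.291 and 0.737, and the call was lost with limma-voom. The call of Fcan01_02915 was lost with library-weighted limma-voom. Leaving out control 12 h replicate 3 or 6, or control 72 h replicate 3 or 4, changed the 568 to 187, 205, 163 and 347, and the 250 to 72, 120, 81 and 109. Without control 60 h replicate 2 the 250 became 158, and DESeq2 and limma-voom called 1639 and 113 in its place. With a block for the replicate number both the 250 and the 568 fell, the 250 to fewer genes than under any of these alternatives.

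Fcan01_06632 was also among the 60 genes called over all time points, at 2.02 ± 0.35 (SE) in log2 units higher with imidacloprid (edgeR adjusted p = 0.00377). It stood at 48.2 CPM ± 33.9 (SD, n = 3) at 12 h and 6.61 ± 4.01 at 72 h in exposed animals. This gene is singled out here after its values were seen.

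Because sampling every 12 h under a cycle of 16 h light and 8 h dark places alternate time points at the same hour of day, the mean of controls at 24, 48 and 72 h was compared with that at 12, 36 and 60 h. Fcan01_04207 was the single gene called, higher by 2.66 ± 0.38 (SE) in log2 units at 24, 48 and 72 h (edgeR adjusted p = 0.00255). Its mean level was 0.722 CPM, below the minimum set for named genes, and it was named after its value was seen. In controls it stood at 0.866 CPM ± 0.264 (SD, n = 3) at 24 h, 0.828 ± 0.643 at 48 h and 2.30 ± 0.170 at 72 h, against 0.164 ± 0.135, 0.256 ± 0.124 and 0.148 ± 0.122 at 12, 36 and 60 h, levels near the floor that leave the size of the difference uncertain. It was also called between 72 and 12 h in controls. A steady change over time enters the comparison of alternate time points too, since 24, 48 and 72 h lie later on average than 12, 36 and 60 h. Hour of day and such drift are therefore not told apart by it. DESeq2 called 198 genes and library-weighted limma-voom 971, and leaving out control 60 h replicate 5, control 48 h replicate 6 or control 24 h replicate 3 gave 77, 66 and 30. For a change of this alternation with imidacloprid, edgeR called 0 genes (790 at an unadjusted p under 0.05), DESeq2 8 and limma-voom 0.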

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

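The alternatives added after the data were examined are 2 surrogate variables, the covariate of the co-varying set, library weights, library totals, the run without irregular titles and the correlation without the co-varying genes. Where a count moved by over 1.5 times, the cause was not tested, except that fits of only 6 libraries have fewer residual degrees of freedom and the stricter filter tests fewer genes. The tests of gene lists were not run, since the identifiers have no names here. Of the log2 fold changes of named genes under the alternatives other than leaving out a library, 280 stayed past the threshold, 29 kept their direction and no longer passed, and 0 changed sign. Runs with a library left out, in which calls of named genes were also lost, are not in this tally. Settings that did not test a gene are not in it either. The filter at 5 CPM in 3 libraries dropped Fcan01_25348, Fcan01_09015 and Fcan01_20402 in this way.

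With DESeq2 as the test, calls for imidacloprid at 12, 24, 36, 48, 60 and 72 h were 13, 20, 55, 53, 16 and 21, over all time points 122, and for its change over time 58. DESeq2 also gave 1639 for time points in controls, 198 for the alternation, 8 for its change and 1097 for controls at 72 against 12 h, and 16 genes called higher at more than 1 time point. Limma-voom gave 113 for time points in controls. DESeq2 size factors, library totals and no filter each gave 1 gene for the change over time. The filter at 5 CPM gave 32 over all time points and 5 for the alternation, and a median Pearson correlation between time points of -0.017 against -0.143. With 1 surrogate variable the counts were 7 at 36 h, 10 at 72 h, 128 over all time points, 2 for the change over time, 627 for time points in controls, 21 for the alternation and 1307 for 72 against 12 h. With 2 they were 7, 10, 116, 2, 509, 11 and 1229. Fits of only the 6 libraries called 14 at 36 h, 0 at 48 h, 0 at 60 h and 158 for 72 against 12 h. The covariate gave 15 at 48 h and 20 for the alternation. Library weights gave 61, 998, 3617, 68 and 19 from 24 to 72 h, 213 over all time points, 4 for the change over time, 2003 for time points in controls and 971 for the alternation. Without the irregular titles named for that run the counts were 3 at 72 h and 377 for time points in controls.

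Leaving out each library in turn gave 0 to 0 calls at 12, 24 and 36 h, 3 to 24 at 48 h, 3 to 5 at 60 h, 0 to 4 at 72 h and 42 to 73 over all time points. It gave 0 to 2 for the change over time, 72 to 331 for time points in controls (72 without control 12 h replicate 3, 81 without control 72 h replicate 3, 109 without control 72 h replicate 4, 120 without control 12 h replicate 6, 158 without control 60 h replicate 2), 1 to 77 for the alternation, 0 to 0 for its change and 163 to 519 for 72 against 12 h.

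The 8 pairs of libraries with the same replicate number at a time point had correlations of their deviations from -0.266 to 0.446 (median -0.103), and 2 were above 0.1. These few pairs gave no sign that the numbers pair libraries of both treatments. Libraries with the same number at different time points were not compared. With the replicate block the counts were 3 at 48 h, 2 at 72 h, 31 over all time points, 39 for time points in controls, 2 for the alternation and 242 for 72 against 12 h.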

Other observations

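Tests of the time course with imidacloprid, of the co-varying set against treatment and depth, of surrogate variables at 48 h, and of the placement of called genes were chosen after the results they bear on were seen. In animals exposed to imidacloprid, 176 genes differed between 72 and 12 h (99 higher, 77 lower, edgeR adjusted p under 0.05) and 207 over the 6 time points. Of the 568 genes called between 72 and 12 h in controls, 550 (96.8%) changed in the same direction in exposed animals, which share no library with them. Both lists shared 99 genes in the same direction, where independent lists would share 2.66. These lists also come from the same fit with a shared spread estimate for each gene, so they are not fully independent. The median change of genes that rose in controls was 2.00 in controls and 0.74 with imidacloprid, and of genes that fell -1.48 and -0.86. The genes were chosen on the control values, which makes the control change larger by selection, and for a difference between both time changes edgeR called 0 genes (503 at an unadjusted p under 0.05; other tools were not run).

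Among the 60 genes called over all time points, 3 pairs had consecutive identifiers, and both members of each went in the same direction. Fcan01_12064 and Fcan01_12065 were lower with imidacloprid, by -0.85 ± 0.15 and -0.41 ± 0.085 (SE) in log2 units, at 203 and 64.6 CPM. Fcan01_18109 and Fcan01_18110 were higher by 1.36 ± 0.25 and 1.23 ± 0.28, at 45.1 and 24.4 CPM. Fcan01_09015 and Fcan01_09016 were lower by -1.89 ± 0.37 and -1.67 ± 0.34. A share of 0.00045 of 100000 random draws of 60 tested genes held as many pairs, which argues against chance placement. If reads of near-identical copies were divided at a fixed ratio, the log ratio of a pair would vary by counting error alone. Its variance was 83.9 and 32.4 times the counting error in the first pairs and 1.99 times in the pair Fcan01_09015 and Fcan01_09016, so this stays open for that pair. These genes were named after their values were seen, and shared regulation of neighbours was not tested.

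Libraries above the gap in the level of the 108 co-varying genes shared groups with libraries below it, and numbered 7 of 18 with imidacloprid and 4 of 18 controls (Fisher's exact test, two-sided, p = 0.471), which leaves a link with treatment open. Depth is argued against, since 21 of the 25 libraries below the gap had totals within the range of those above it. A single source of RNA in different amounts would keep the ratios between genes, and is argued against for all 11 libraries together, as the lowest correlation across these genes was 0.278: control 36 h replicate 5, imidacloprid 12 h replicate 6 and imidacloprid 60 h replicate 3 had median correlations of 0.454, 0.682 and 0.704 with the others. These correlated more with each other, at 0.944 between both imidacloprid libraries and at 0.789 and 0.709 between these and control 36 h replicate 5. Between the other 8 libraries the lowest correlation was 0.871, so a single source may remain for these 8, as may a state of the animals, which was not tested.

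At 48 h 2819 genes had an unadjusted p under 0.05, where 980 would by chance, but 814 without imidacloprid replicate 5 and 6127 without imidacloprid replicate 3, so the excess hangs on single libraries. The uneven level of the co-varying set, high in control replicates 2 and 6, is argued against as the cause, since 4148 genes passed with that level in the model. Scaling is argued against too, with 2450 genes under DESeq2 size factors and 2181 under library totals. With 2 surrogate variables the number fell to 578, so a candidate explanation is variation that also separates libraries of the same group. Whether imidacloprid adds to the wide excess stays open, apart from the called genes, 5 of which were called in that fit too.

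Other groupings of the same libraries were tried for each count of calls. Over all time points, where the real count was 60, 2 of 100 regroupings gave as many, the real 1 included. This argues against chance but does not exclude it. The highest other regrouping called 697, which points to a structure of the samples beyond treatment. For time points in controls 1 of 100 gave 250 or more, and the highest other gave 43, which argues against chance. For the alternation in controls 5 of 100 gave 1 or more, with 297 the highest other, so chance stays open. For the change over time and the change of the alternation, with 0 calls, all 100 gave as many, and the highest others gave 657 and 484. For comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. By edgeR, the real counts at 12, 24 and 36 h were 0 (unadjusted p under 0.05 in 649, 341 and 2032 genes; 13, 20 and 55 called by DESeq2 and 0 by limma-voom), with 0 the highest other. At 48 and 60 h they were 7 and 4, with 0 the highest other. At 72 h the real count was 5 and the highest other 105, which points to a structure of the samples. For controls at 72 against 12 h the real count was 568, with 0 the highest other.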
